A study of Homo sapiens with 6 samples.

How the data were processed

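RNA was measured in cultured smooth muscle cells of the human aorta (HASMCs, primary cells and not an established line) that carried an adenovirus for LacZ or for TFEB. Per the labels' protocols, cells were infected at a multiplicity of infection of 30, collected after 48 h, and 400 ng of total RNA per sample was turned into biotinylated cDNA for a whole-transcript Affymetrix array. The 6 arrays were grouped by the virus their labels name, 3 LacZ and 3 TFEB, and 0 columns of the table were left without a sample.

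The deposited table holds log2 levels, 1 per array and transcript cluster, in 53617 rows. Per the submitters' processing notes, RMA and limma were used, and their versions and settings are not given in the sources used here. As commonly run, RMA corrects the background, quantile-normalizes the probes between arrays and summarises them per row, which equalises the arrays' overall distributions and compresses changes of dim rows. The scale was read from the values, which ran from 0.21 to 13.7 with array medians of 2.55 to 2.59. The authors' table carries no detection calls, so a level near the bottom of the scale cannot be told from background, and a fold from such a level is a ratio of RMA values only. The number of arrays, 3 per group, limits the precision.

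Genes were named through the platform annotation. It lists 25713 of the rows, 23862 of them with 1 gene and 1851 with several, and 27904 rows are unnamed here. By gene ID, 22569 rows matched the RefSeq gene table of assembly GRCh38.p14, which was used for names alone and updated 90 symbols. The array's genome build is not given in the sources used here, so no coordinates are printed. Control rows could not be told apart from other unlisted rows, and all unlisted rows stayed out of the gene test, as did rows that name several genes, XIST, TSIX and Y-linked genes. For 629 genes with several rows, the row with the highest mean over all 6 arrays was taken, which left 22353 genes. Rows of near-identical families, such as the late cornified envelope genes, can share target sequence, so levels of single members are uncertain.

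TFEB minus LacZ was fitted per gene with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 on the deposited log2 values with no further scaling or filter. A gene counted as changed when its Benjamini-Hochberg adjusted p over all genes was under 0.05, and a stricter count took changes of at least 2-fold. For 26 gene lists with at least 5 measured members, camera with its preset correlation of 0.01 tested whether members moved further up or down together than other genes. The test was two-sided and Benjamini-Hochberg adjusted over the lists. Rises and falls within a list offset each other in it, so a list that did not pass can still hold many changed members. Of these lists, 12 passed with the preset correlation and none of those calls held with an estimated correlation (0 lists, 5 at an unadjusted p under 0.05, against 20 by fry, a rotation test that does not compare a list with other genes). Member counts are given over all genes tested and adjusted over the list alone. Of all 22353 genes tested 1430 rose and 745 fell, the background beside which these counts stand.

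The comparison, the lists and the rule for named genes were fixed before the data were examined. The rule took TFEB, BCL2, the 6 largest rises and 6 largest falls among called genes whose arrays do not overlap between the groups, and up to 3 called members per list with the smallest adjusted p, 78 genes in all. Loci with only a provisional symbol were counted and not named. The alternatives tried were the replicate number as a block, quantile normalization, centring on the median gene, leaving out the 33.3% of genes with the lowest mean, an intensity trend with robust variance, array weights, the mean of a gene's rows, all rows of the table, other list tests, and leaving out each array in turn. Further lists of keratinocyte, melanocyte, B cell, skin barrier, pigment cell, Notch ligand, interferon-induced and type I interferon genes were written after the main results had been seen.

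The gene test was tested on simulated data for this comparison, in which 200 of 22353 genes were shifted. It recovered 10% of 50 genes shifted by 0.5 on the log2 scale, 76% of 50 shifted by 1, 98% of 50 shifted by 2 and 100% of 50 shifted by 4. Of its 154 calls, 12 were false. The list test found 2 of 2 lists shifted by 0.3 and called 0 of 24 other lists. Each simulated gene was drawn independently, so false list calls from genes that move together could not appear. Fewer genes were shifted than were called in the data (2175), and the recovered shares depend on that number.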

Results

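Smooth muscle cells of the human aorta (HASMCs), the contractile and matrix-producing cells of the vessel wall, were infected with an adenovirus carrying TFEB or with a control adenovirus. TFEB is a transcription factor of the MiT/TFE family that binds promoters of lysosomal and autophagy genes. LacZ, carried by the control virus, encodes bacterial beta-galactosidase. Cells were collected 48 h after infection at a multiplicity of infection of 30, and each group held 3 arrays. Over 22353 genes, Pearson's r was 0.991 to 0.992 between arrays of 1 group and 0.978 to 0.980 between arrays of different groups, values that run across genes, which are not independent replicates. The first principal component, with 58.0% of the variance, separated the groups. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

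The comparison asks which transcripts differ when TFEB is overexpressed. The row of TFEB itself averaged 4.25 ± 0.53 (log2 level, SD, n = 3) in the TFEB arrays and 3.38 ± 0.13 (SD, n = 3) in the LacZ arrays. The log2 change was 0.87 (SE 0.25, limma adjusted p = 0.0812), a 1.83-fold difference that missed the threshold. TFEB replicates 1, 2 and 3 read 4.56, 3.64 and 4.55, each above the LacZ values of 3.40, 3.49 and 3.24. Without TFEB replicate 2 the log2 change of TFEB was 1.18 with an adjusted p of 0.0054, and an intensity trend with robust variance gave an adjusted p of 0.0424. Whether the row's probes lie in the sequence that the virus carried is not given in the sources used here.

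In the TFEB arrays 1430 genes rose and 745 fell at an adjusted p under 0.05 (limma), and 608 rose and 99 fell by at least 2-fold. The largest rise was that of ATP6V0D2, a subunit of the vacuolar proton pump known from osteoclasts, from a log2 level of 2.28 ± 0.34 (SD, n = 3) to 9.35 ± 0.12 (SD, n = 3), 134-fold (adjusted p = 1.13e-05). CNTFR, the receptor of ciliary neurotrophic factor, rose 108-fold, the epithelial serpin SERPINB12 48.9-fold, the embryonic globin HBZ 47.5-fold, the lectin CLEC17A 46.3-fold and the cornified envelope gene LCE1A 44.1-fold, all from log2 levels of 1.82 to 2.50 in LacZ arrays, near the bottom of the scale. A provisional locus that also lay among the largest rises is counted and not named. The largest falls were those of the interferon-induced genes OAS2 (log2 change -2.98, 7.90-fold lower), MX2 (-2.67), OAS1 (-2.55), IFIT2 (-2.50), IFIT1 (-2.48) and IFIT3 (-2.27). Of the 608 genes that rose at least 2-fold, 319 (52.5%) lay below the median gene level of 4.01 in the LacZ arrays, against 50.7% of all genes tested, and 25 of the 99 that fell at least 2-fold lay below it in the TFEB arrays.

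**Figure D1:**
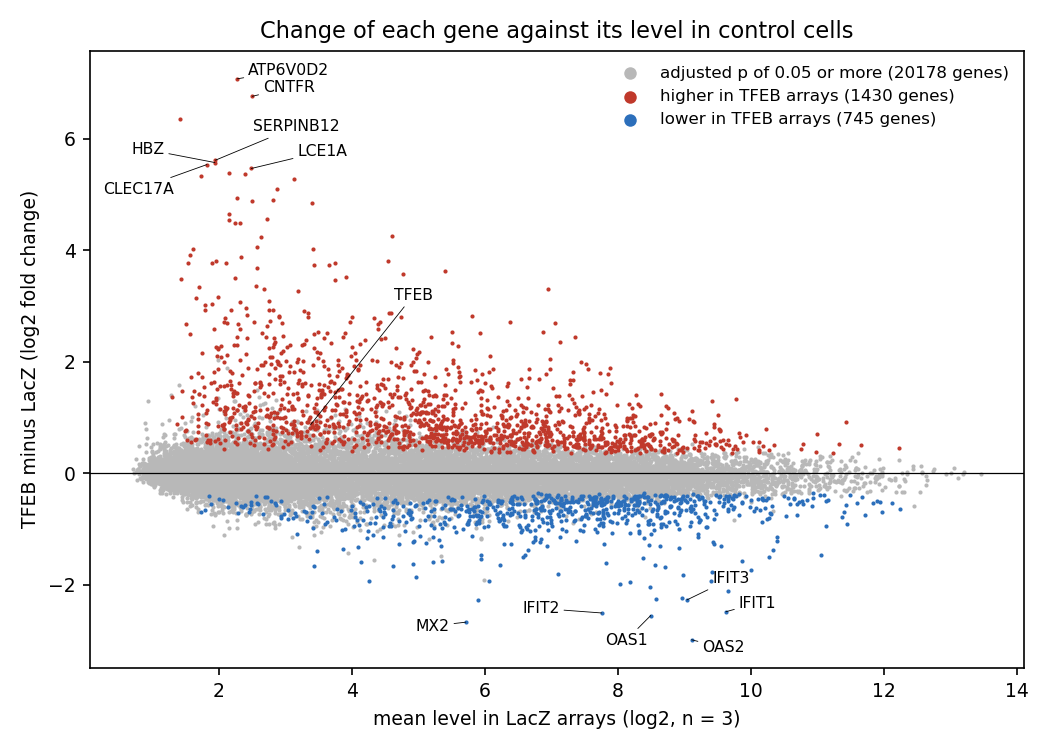
Each point is a gene, with its mean log2 level in the 3 LacZ arrays on the x axis and its log2 change, TFEB minus LacZ, on the y axis. The 1430 red genes rose and the 745 blue genes fell at an adjusted p under 0.05, and the largest rises, such as ATP6V0D2 at 7.07, start from low levels.

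Rises made up 65.7% of the called genes on the deposited scale, 57.4% after quantile normalization and 37.7% after centring each array on its median gene, which moved the median change of all genes from -0.02 to -0.15. Among changes of at least 2-fold, centring left 506 rises and 187 falls. An intensity trend with robust variance called 3282 genes in place of 2175. Leaving out any 1 array lowered the count to between 1324 (without LacZ replicate 2) and 1540 (without TFEB replicate 3), with 942 to 1093 rises and 359 to 447 falls.

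Vacuolar proton pump subunits, parts of the ATPase that acidifies lysosomes, were higher as a group in the TFEB arrays. Of 19 measured subunits 13 rose (13 adjusted over the list alone), with a median log2 change of 0.85, or 0.72 after centring. Besides ATP6V0D2, ATP6V0A1 rose by 1.41 (SE 0.11, 2.67-fold) and ATP6V0D1 by 1.21 (SE 0.10, 2.32-fold) on the log2 scale. The list passed camera (adjusted p = 4.73e-11), and the adjusted p = 0.0665 with an estimated correlation. Lysosomal membrane proteins and transporters rose in 11 of 25 measured members (11 adjusted over the list alone), median log2 change 0.29, or 0.16 after centring (camera adjusted p = 3.83e-06, and adjusted p = 0.0665 with an estimated correlation). They included the cholesterol exporter NPC1, which rose from 7.71 ± 0.07 to 8.86 ± 0.10 (log2 level, SD, n = 3 per group), CLN3, the Batten disease protein (log2 change 1.16), and MCOLN1, the lysosomal calcium channel (1.39).

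Lysosomal hydrolases and their cofactors rose in 7 of 39 measured members (10 rose and 2 fell adjusted over the list alone). The list passed camera in the upward direction (adjusted p = 0.00996, and adjusted p = 0.254 with an estimated correlation), with a median log2 change of 0.09 that turned to -0.04 after centring and was 0.05 without LacZ replicate 2. PLA2G15, a lysosomal phospholipase, rose 3.67-fold (log2 change 1.88, SE 0.09), GM2A, the activator of ganglioside breakdown, 2.89-fold and the collagen-degrading protease CTSK 2.52-fold. CTSK reached a log2 level of 11.11 ± 0.07 (SD, n = 3) against 9.78 ± 0.07 (SD, n = 3) in LacZ arrays.

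**Figure D2:**
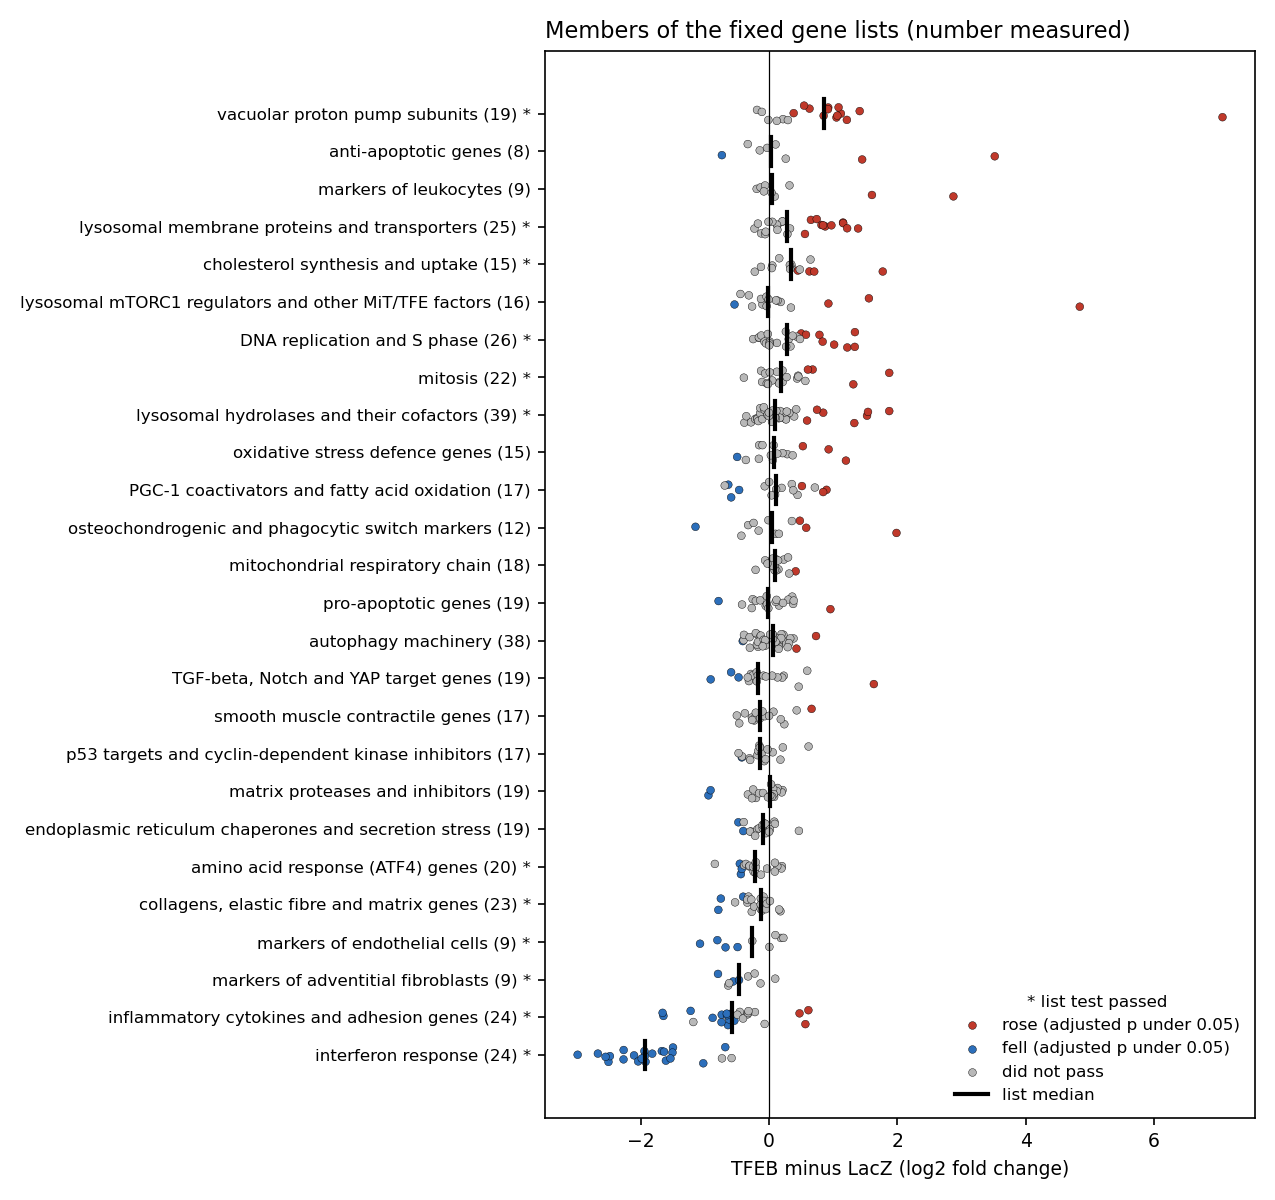
Each point is a measured member of a fixed gene list, with its log2 change, TFEB minus LacZ, on the x axis and the number measured beside the list's name. Red members rose and blue members fell at an adjusted p under 0.05, grey members did not pass, black bars are medians and an asterisk marks lists past camera at its preset correlation. Proton pump subunits (median 0.85) and interferon response genes (median -1.93) lie at opposite ends.

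Autophagy machinery changed in few members, beside 2175 changed of 22353 genes tested. Of 38 measured, 2 rose and 1 fell (2 and 1 adjusted over the list alone), the median log2 change was 0.06, or -0.07 after centring, and the list did not pass camera (adjusted p = 0.648). Its median was 0.03 without LacZ replicate 1, TFEB replicate 1 or TFEB replicate 2. VPS18, a tethering subunit for fusion with lysosomes, rose by 0.73 (SE 0.11, adjusted p = 0.00638) on the log2 scale. PIK3C3, the class III lipid kinase, fell by 0.41 (adjusted p = 0.0307) and the lipid transfer gene ATG2A rose by 0.43 (adjusted p = 0.0377). PIK3C3 and ATG2A missed the threshold without any 1 of the 6 arrays (adjusted p = 0.0796 to 0.0995 and 0.0610 to 0.109), and ATG2A also missed it after quantile normalization (0.0685) and centring (0.0942).

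Lysosomal mTORC1 regulators and other MiT/TFE factors rose in 3 and fell in 1 of 16 members (3 and 1 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.291). Its median log2 change was -0.02, or -0.15 after centring, while its mean was 0.39 and its test pointed upward. The median turned to 0.04 without LacZ replicate 2 or LacZ replicate 3 and to 0.07 without TFEB replicate 3, and it lay between -0.06 and -0.01 without any other array. The Rag GTPase gene RRAGD rose 28.7-fold, from 3.40 ± 0.36 to 8.25 ± 0.05 (log2 level, SD, n = 3 per group, adjusted p = 2.44e-05), its relative RRAGC 1.90-fold, and FNIP2, which encodes a partner of folliculin, 2.95-fold. TFE3, the member that fell, was chosen after its values were seen and is a paralogue of TFEB.

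Cholesterol synthesis and uptake genes rose in 4 of 15 measured members (7 adjusted over the list alone), median log2 change 0.35, or 0.22 after centring (camera adjusted p = 4.05e-04, and adjusted p = 0.204 with an estimated correlation). LSS, which closes the sterol ring, rose 3.42-fold, from 7.85 ± 0.04 to 9.63 ± 0.05 (log2 level, SD, n = 3 per group). IDI1, the isomerase of isoprenoid synthesis, rose by 0.63 (adjusted p = 0.0156) and INSIG1, a brake on sterol synthesis, by 0.71 (adjusted p = 0.0251). IDI1 missed the threshold without LacZ replicate 1 or 2 or TFEB replicate 1 or 2 (adjusted p = 0.0546 to 0.0609), and INSIG1 without LacZ replicate 2 or 3 or TFEB replicate 1 or 2 (0.0794 to 0.0854).

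Genes of PGC-1 coactivators and fatty acid oxidation moved both ways, 3 up and 3 down of 17 (7 and 4 adjusted over the list alone), with a median log2 change of 0.11, or -0.02 after centring (camera adjusted p = 0.166). That median was 0.17 without LacZ replicate 1, 0.06 without LacZ replicate 2 and 0.22 without TFEB replicate 3. CPT1A, the entry enzyme of mitochondrial fatty acid oxidation, rose 1.86-fold and the coactivator PPARGC1A 1.80-fold. ACADVL, an acyl-CoA dehydrogenase, fell by 0.46 (adjusted p = 0.0205) on the log2 scale and missed the threshold without any 1 array (0.0532 to 0.0778). In the mitochondrial respiratory chain 1 of 18 measured members rose (1 adjusted over the list alone), median 0.09, or -0.04 after centring (camera adjusted p = 0.0787, or 0.0294 with an intensity trend and robust variance, and adjusted p = 0.333 with an estimated correlation). That member, COX5A of cytochrome oxidase, rose by 0.42 (adjusted p = 0.0324) and missed the threshold without any 1 array (0.0532 to 0.108) and after centring (0.0930). Oxidative stress defence genes rose in 3 and fell in 1 of 15 (4 and 2 adjusted over the list alone), with a median log2 change of 0.07, or -0.06 after centring (camera adjusted p = 0.160). The median of that list was 0.03 to 0.04 without LacZ replicate 2 or TFEB replicate 2, and 0.12 to 0.14 without LacZ replicate 1, TFEB replicate 1 or TFEB replicate 3. The heme-degrading enzyme gene HMOX1 rose 2.30-fold, the glutathione reductase gene GSR 1.91-fold and the thioredoxin gene TXN 1.44-fold. TXN missed the threshold without LacZ replicate 3 or TFEB replicate 1 (adjusted p = 0.0519 and 0.0517).

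Interferon response genes, which cells induce against viruses, were lower in the TFEB arrays. Of 24 measured members 22 fell (24 adjusted over the list alone), with a median log2 change of -1.93 (camera adjusted p = 3.31e-22, and adjusted p = 0.204 with an estimated correlation). The mean log2 level of the list was 8.07, 8.34 and 8.06 in the LacZ arrays and 6.15, 6.05 and 6.79 in the TFEB arrays. IFIT2, an RNA-binding antiviral protein gene, fell from 7.75 ± 0.08 to 5.25 ± 0.18 (log2 level, SD, n = 3 per group, 5.66-fold lower), and RSAD2, the gene of viperin, was 4.80-fold lower. Both groups carried an adenovirus, and no uninfected cells were analysed here.

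Inflammatory cytokine and adhesion genes fell in 12 and rose in 3 of 24 measured members (16 and 3 adjusted over the list alone), median log2 change -0.57 (camera adjusted p = 2.45e-07, and adjusted p = 0.171 with an estimated correlation). The chemokine gene CCL20 was 3.13-fold lower, the leukocyte adhesion gene VCAM1 2.33-fold lower and the prostaglandin synthase gene PTGS2 1.84-fold lower. VCAM1 fell from 9.43 ± 0.06 to 8.21 ± 0.10 (log2 level, SD, n = 3 per group). Endothelial cell markers were lower in the same arrays, with 4 of 9 measured members falling (4 adjusted over the list alone) and a median log2 change of -0.26, or -0.38 after quantile normalization and -0.39 after centring (camera adjusted p = 0.0394, and adjusted p = 0.254 with an estimated correlation). The junction gene CDH5 was 2.11-fold lower, the receptor genes TEK 1.75-fold and KDR 1.40-fold lower. The endothelial list missed the threshold after centring (adjusted p = 0.0709) and without LacZ replicate 3, TFEB replicate 2 or TFEB replicate 3 (0.0529 to 0.0968, medians -0.31 to -0.07, against -0.40 without TFEB replicate 1), and KDR missed it without any 1 array (0.0555 to 0.0888).

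Genes of DNA replication and S phase rose in 8 of 26 measured members (9 adjusted over the list alone), median log2 change 0.29, or 0.19 after quantile normalization and 0.16 after centring (camera adjusted p = 5.31e-04, and adjusted p = 0.148 with an estimated correlation). The cyclin E genes CCNE1 and CCNE2 rose 2.33-fold and 2.53-fold, and CDT1, a replication licensing factor, 2.53-fold. CCNE2 started from a log2 level of 2.95 in LacZ arrays, below the median gene level of 4.01. Mitosis genes rose in 4 of 22 (4 adjusted over the list alone), median 0.19, or 0.09 after quantile normalization and 0.05 after centring (camera adjusted p = 0.0130, and adjusted p = 0.333 with an estimated correlation). The kinetochore motor gene CENPE rose 3.67-fold, the kinase gene PLK1 2.49-fold and CENPF 1.60-fold, CENPF from a log2 level of 3.23 in LacZ arrays. The mitosis list missed the threshold after quantile normalization (adjusted p = 0.0756) and without LacZ replicate 3 (0.110, median 0.18).

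Among p53 targets and cyclin-dependent kinase inhibitors 1 of 17 measured members changed (1 adjusted over the list alone), and the list, with a median log2 change of -0.14, or -0.27 after centring, did not pass camera (adjusted p = 0.0951), though it did with an intensity trend and robust variance (0.0392). For that list the adjusted p = 0.254 with an estimated correlation. That member, TP53INP1, fell by 0.42 (adjusted p = 0.0357) on the log2 scale and missed the threshold without any 1 array (0.0669 to 0.112). Amino acid response genes, targets of ATF4, fell in 3 of 20 (6 adjusted over the list alone), median log2 change -0.22, or -0.35 after centring (camera adjusted p = 0.00316, and adjusted p = 0.204 with an estimated correlation). Its members DDIT4, an mTORC1 inhibitor, SESN2, a leucine sensor, and the asparagine synthetase gene ASNS fell by 0.44, 0.45 and 0.42, and each missed the threshold without any 1 array (adjusted p = 0.0577 to 0.121 over these genes and arrays). Endoplasmic reticulum chaperones and secretion stress genes fell in 2 of 19 (2 adjusted over the list alone), median -0.10, or -0.23 after centring (camera adjusted p = 0.0787). The list passed after centring (0.0439), with an intensity trend and robust variance (0.0215) and without TFEB replicate 1 (0.0359, median -0.12), and had an adjusted p = 0.350 with an estimated correlation. HERPUD1 fell by 0.40 and the stress sensor gene ERN1 by 0.48. HERPUD1 missed the threshold without any 1 array (adjusted p = 0.0674 to 0.0986), and ERN1 without any 1 of them but TFEB replicate 3 (0.0799 to 0.120).

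BCL2, which holds back the mitochondrial path of cell death, rose from 3.55 ± 0.34 to 5.01 ± 0.19 (log2 level, SD, n = 3 per group, 2.74-fold, adjusted p = 0.00432). Its relative BCL2A1 rose 11.5-fold, from 3.90 ± 0.23 to 7.42 ± 0.26, and CFLAR, an inhibitor of caspase-8, was 1.66-fold lower (adjusted p = 0.00504). With these, 2 of 8 measured anti-apoptotic genes rose and 1 fell (2 and 2 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.389, median log2 change 0.04, or -0.09 after centring). Its median was 0.02 without LacZ replicate 1, 0.0079 without TFEB replicate 1 and 0.07 without TFEB replicate 2. Of 19 pro-apoptotic genes 1 rose and 1 fell (1 and 1 adjusted over the list alone). BBC3, the gene of PUMA, rose 1.94-fold (adjusted p = 0.00277), and PMAIP1, the gene of NOXA, was 1.72-fold lower (adjusted p = 0.0337). PMAIP1 missed the threshold without any 1 array but TFEB replicate 2 (0.0545 to 0.101). The pro-apoptotic list had a median log2 change of -0.01, or -0.03 after quantile normalization and -0.14 after centring, and a mean of 0.04 with a test that pointed upward (camera adjusted p = 0.798), and the median was above 0 without LacZ replicate 1 (0.08) or 2 (0.05) or TFEB replicate 2 (0.01) or 3 (0.03), and -0.0025 without TFEB replicate 1.

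**Figure D3:**
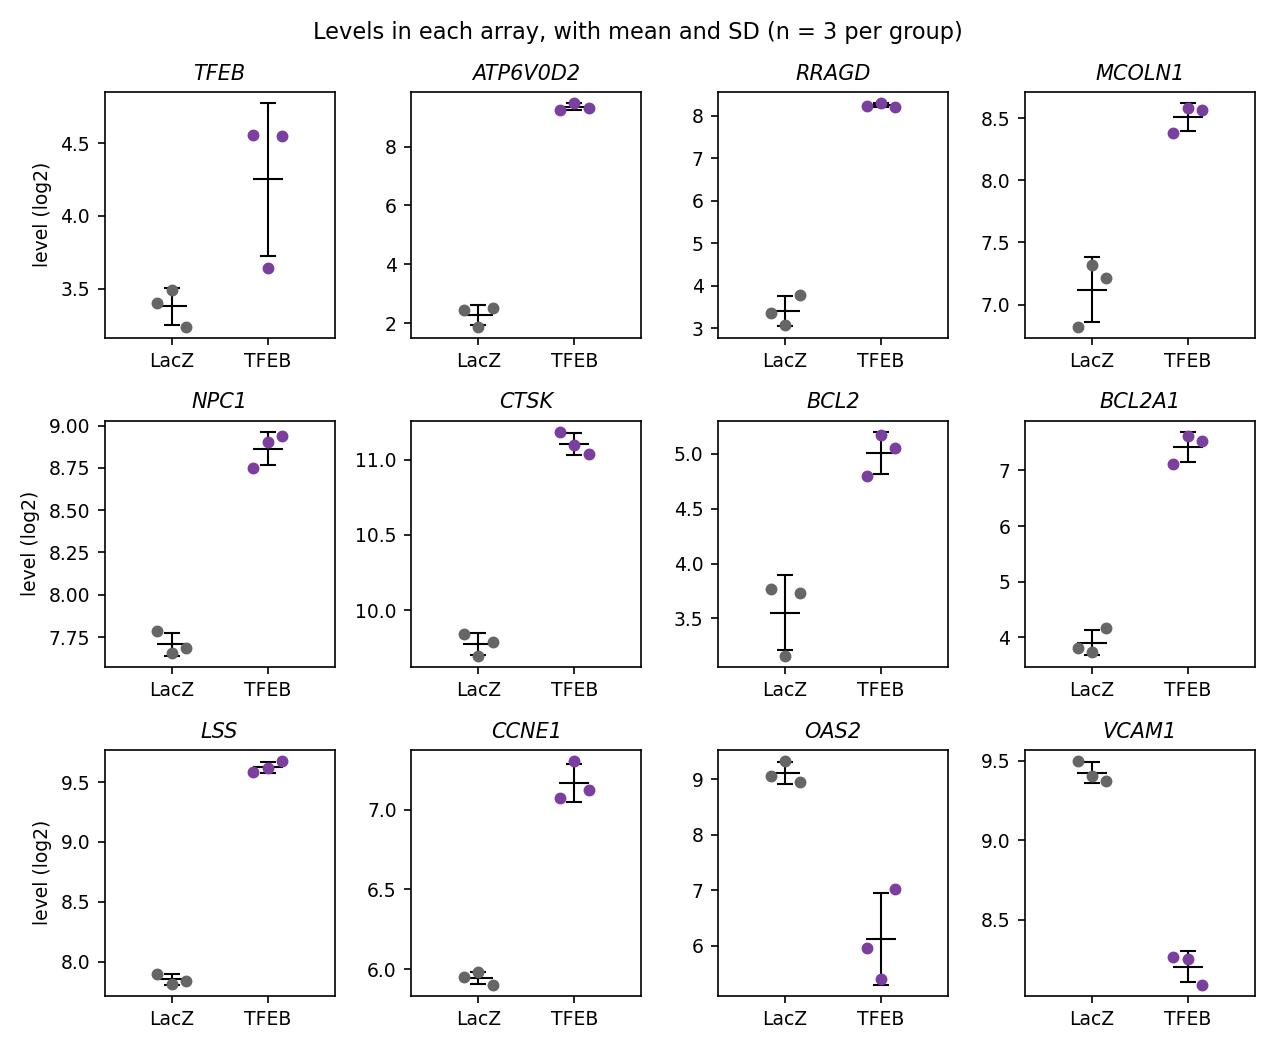
Dots are log2 levels of single arrays, with LacZ and TFEB on the x axis and a y axis of its own in each panel, bars are the mean and SD of 3 arrays, and none of the y axes starts at 0. The 3 TFEB arrays lie above the 3 LacZ arrays for the first 10 genes, TFEB itself included, and below them for OAS2 and VCAM1.

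Smooth muscle contractile genes changed in 1 of 17 measured members (1 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.322, median log2 change -0.14, or -0.27 after centring and also -0.27 without TFEB replicate 1). That member, the smoothelin gene SMTN, rose by 0.66 (adjusted p = 0.0270) and missed the threshold without LacZ replicate 1 or 2 or TFEB replicate 1 or 3 (0.0713 to 0.0824). Collagen, elastic fibre and matrix genes fell in 3 of 23 (5 adjusted over the list alone), median -0.13, or -0.26 after centring (camera adjusted p = 8.68e-04, and adjusted p = 0.333 with an estimated correlation). The matricellular gene THBS1 was 1.68-fold lower, from 11.72 ± 0.04 to 10.97 ± 0.07 (log2 level, SD, n = 3 per group). COL8A1 and COL5A2 fell by 0.79 and 0.40, COL8A1 missing the threshold without TFEB replicate 1, 2 or 3 (adjusted p = 0.0607 to 0.0724) and COL5A2 without any 1 array (0.0726 to 0.121).

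Markers of adventitial fibroblasts, the cells outside the muscle layer, were lower in the same arrays as these matrix genes. They fell in 3 of 9 measured members (6 adjusted over the list alone), median log2 change -0.47 (camera adjusted p = 5.61e-04, and adjusted p = 0.148 with an estimated correlation). The scavenger receptor gene SCARA5 was 1.73-fold lower, DPT 1.47-fold and PI16 1.38-fold lower. DPT missed the threshold without any 1 array but TFEB replicate 2 (adjusted p = 0.0704 to 0.100), and PI16 without any 1 array (0.0655 to 0.117). Leukocyte markers rose in 2 of 9 (2 adjusted over the list alone), median 0.04, or -0.09 after centring (camera adjusted p = 0.177), and 0.08 to 0.09 without LacZ replicate 1, TFEB replicate 1 or TFEB replicate 3. The B cell receptor gene CD79A rose 7.34-fold and the macrophage receptor gene CSF1R 3.04-fold, CSF1R from a log2 level of 3.25 in LacZ arrays, below the median gene level of 4.01.

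Matrix proteases and inhibitors fell in 2 of 19 measured members (3 adjusted over the list alone), the aggrecan-cleaving proteases ADAMTS1 (1.92-fold lower) and ADAMTS5 (1.88-fold lower). The list did not pass camera (adjusted p = 0.251), and its median log2 change of 0.02 differed in sign from its mean of -0.11 and its test, as it did from the medians after quantile normalization (-0.02) and centring (-0.11). Without LacZ replicate 1 or TFEB replicate 2 that median was -0.03 and -0.06, and without LacZ replicate 3 or TFEB replicate 3 it was 0.01 and 0.04. TGF-beta, Notch and YAP target genes rose in 1 and fell in 3 of 19 (3 and 5 adjusted over the list alone, camera adjusted p = 0.251, median -0.17, or -0.30 after centring, -0.05 without LacZ replicate 3 and -0.10 without TFEB replicate 3). ANKRD1, a target of YAP, rose 3.11-fold, while CCN2, also a target of YAP and of TGF-beta, was 1.88-fold lower and the Notch ligand gene JAG1 fell by 0.59 on the log2 scale. JAG1 missed the threshold with the replicate number as a block (limma adjusted p = 0.0521). Osteochondrogenic and phagocytic switch markers rose in 3 and fell in 1 of 12 (4 and 2 adjusted over the list alone, camera adjusted p = 0.709, median 0.05, or -0.03 after quantile normalization and -0.08 after centring). Without LacZ replicate 3, TFEB replicate 1 and TFEB replicate 2 in turn, the median of these markers was 0.03, 0.01 and 0.09. SPP1, the gene of osteopontin, rose 3.97-fold from a log2 level of 3.17 ± 0.67 (SD, n = 3) in LacZ arrays, below the median gene level of 4.01. The growth factor gene BMP2 rose by 0.58 on the log2 scale, and TNFRSF11B, the gene of osteoprotegerin, was 2.21-fold lower. BMP2 missed the threshold without LacZ replicate 2 (adjusted p = 0.0506).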

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

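The tests of other cell types, dim rows, scaling, a single array, the reaction to the LacZ virus and probe positions were chosen after the results were seen, and that of other splits before. Those of virus dose and a wrong label were listed as planned. Their wording names the small rise of the TFEB row, so that result had been seen. Signals stood outside the gene test: 166 rows with no gene listed rose at least 2-fold and 58 fell. Among rows that name several genes, 25 rose at least 2-fold and 6 fell.

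Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many changed genes, genes changed at least 2-fold, or gene lists as the real split. It called 2175 genes, 707 genes and 12 lists, and the highest other split 0 genes (limma, 819 at an unadjusted p under 0.05), 0 genes and 6 lists. With 10 splits the share cannot fall under 0.05. Each other split holds LacZ and TFEB arrays on both sides. A difference between the groups then adds to the spread within each side and lowers the calls, so these counts are no baseline for the real split.

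Below the median gene level in LacZ arrays lay 319 of the 608 genes that rose at least 2-fold (52.5%, against 50.7% of all genes tested) and 125 of the 166 that rose at least 4-fold (75.3%), a difference between shares that was not tested. RNA of keratinocytes would raise keratin genes, but 7.14% of keratinocyte markers rose (1 of 14, SFN, 1 adjusted over the list alone, and 11 of 56 with the skin barrier genes added), with KRT5 at 2.21 in LacZ and 2.35 in TFEB arrays and KRT14 at 2.58 and 2.66. Of B cell markers 0% rose (limma, 0 of 14, also 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, and 2 of 23 with the fixed leukocyte markers added), with IGHM at 3.47 and 3.57, and of melanocyte markers 16.7% (2 of 12, 3 adjusted over the list alone, and 7 of 22 with pigment cell genes added), with MLANA at 1.78 and 1.82. These marker lists left out genes that rose: IVL and LORICRIN (keratinocytes), CD79A (B cells), and TYR, TRPM1 and TSPAN10 (melanocytes). The shares depend on which genes are listed, and leaving out risen genes lowers them, so the shares alone cannot decide for any of these cell types. Of the listed markers, KRT5, KRT14, IGHM and MLANA did not pass the threshold. Noise of dim rows would call falls as often as rises, but genes called 2-fold lower that were dim in TFEB arrays were 7.84% as many (25 against 319). Shared target sequence among related genes stays open, and so does, as a hypothesis, an effect of TFEB overexpression on genes that HASMCs keep low.

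Interferon response genes were lower in all TFEB arrays, at list means of 6.05 to 6.79 against 8.06 to 8.34. The values argue against a single outlying array as the source, since the median log2 change closest to 0 was -1.75, without TFEB replicate 2. Quantile normalization gave -1.96, but RMA commonly includes that step, so a repeat could hardly move the median. Centring gave -2.06. Array medians over all genes, 3.93 to 4.08, differed far less than the list did, so the deposited values hold no overall shift of that size. RMA commonly draws the arrays together, so these medians cannot speak to a shift before it. A stronger interferon reaction to the LacZ virus and a lower one under TFEB cannot be told apart, because 0 uninfected arrays were analysed here. Both may contribute, and neither is shown.

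The row of TFEB itself differed by only 0.87 on the log2 scale. Less virus in TFEB replicate 2, the lowest TFEB array, would lower the proton pump subunits there if these still followed the dose. Their mean lay 0.02 above that of the other TFEB arrays (0.0192), against a difference between the groups of 0.98. Whether the subunits followed the dose was not tested, so a lower dose there stays open. A control array labelled TFEB is argued against, since the lowest TFEB array lay 0.92 (0.924) above the highest LacZ array in the mean of the pump subunits. Probes outside the sequence that the virus carried may explain the small rise, and with 0 probe positions in the tables used this cannot be told apart from a small rise in the transcript.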

How the results depend on the processing

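The alternatives were planned except for those on interferon genes, chosen after seeing the data. The balance of calls turned after centring, from 65.7% rises to 37.7% (1118 rose, 1849 fell), and so did the medians of 9 lists, 1 of them past camera (lysosomal hydrolases, 0.09 to -0.04), and of 2 lists after quantile normalization. No named gene changed sign, and no list test that passed changed direction (that of the osteochondrogenic list, which did not pass, pointed down with fry, adjusted p = 0.555). Of the 78 named genes 55 kept their direction and side of the threshold in every alternative, 22 lost their call in some, mostly without 1 array or with the block (20 genes), and TFEB gained it in some. The count of changed genes, 2175, was 1302 with the replicate block (1255 shared), 3282 with an intensity trend and robust variance (2108 shared) and 1324 to 1540 without 1 array, where fewer arrays raise the p-values. Calls kept without each array in turn numbered 1083. Quantile normalization gave 2299, centring 2967, leaving out the dimmest 33.3% of genes 2821 and all rows of the table, control rows included since these are not marked, 1627. The count of falling genes, 745, was 322 with the block, 1849 after centring, 1375 with the trend, 430 over all rows and 359 to 447 without 1 array, and rising genes, 1430, numbered 942 to 1093 without 1 array. Genes changed at least 2-fold stayed at 655 to 742 in every alternative that gave them, though falls of at least 2-fold, 99, numbered 187 after centring and 61 without the interferon genes. The TFEB row kept a log2 change of 0.87 with the trend, now past the threshold (adjusted p = 0.0424, with a range over alternatives of 0.0054 to 0.209), and 0.72 to 1.18 without 1 array, past the threshold without TFEB replicate 2. Of 26 gene lists, 12 passed in the main test, 0 with an estimated correlation (camera, 5 at an unadjusted p under 0.05), 20 with fry and 10 to 13 without 1 array. The other list settings gave 11 to 15 lists, and leaving out those dim genes took the leukocyte markers below 5 members. Centring subtracts 1 value per array from all its genes, so it moved the change of every gene by the same amount. Proton pump subunits went from a median of 0.85 to 0.72 and interferon response genes from -1.93 to -2.06. The list medians that turned after centring follow from that shift. For the other differences the cause was not tested beyond the number of arrays and the construction of the list tests. Replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated at 0.00939, -0.0427 and -0.0297, and the block ended 1 list call, that of endothelial markers (adjusted p = 0.0666). The promoter motif test and its alternatives were not run, since no genome was used here. Without detection calls, signal over background limits what can be said of dim genes.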

Other observations

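The lists and tests in this part were all written after the main results had been seen. Genes of the skin barrier, most of them dim in HASMCs (2 of 44 above the median gene level in LacZ arrays), rose in 10 of 44 measured members (10 adjusted over the list alone). Besides SERPINB12 and LCE1A these were NIPAL4 (log2 change 5.09), the lipoxygenase gene ALOXE3 (4.56), the involucrin gene IVL (4.49), LCE1C (3.81), LCE2C (3.14), TCHH (2.67), LORICRIN (2.30) and LCE2A (1.59). The skin barrier, Notch ligand and pigment cell lists were written because members stood among the largest rises, so their counts are not independent evidence, and no list test is given for them. Of 5 Notch ligand genes, DLL3 (5.37), DLL1 (4.94) and JAG2 (3.27) rose and JAG1 fell (-0.59), with 3 and 1 adjusted over the list alone.

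Pigment cell genes rose in 7 of 19 measured members (8 rose and 2 fell adjusted over the list alone). They were TYR (log2 change 3.78), the tyrosinase gene, TRPM1 (3.77), TSPAN10 (3.73), PMEL (2.33), BIRC7 (1.64), RAB38 (1.27) and GPNMB (0.88), and 7 of the 19 lay above the median gene level in LacZ arrays. Several are known targets of MITF, a paralogue of TFEB that reads the same E-box. A candidate explanation, drawn from these risen genes and not tested, is that overexpressed TFEB acts at sites of MITF. The other 12 measured members of the list did not pass, among them TYRP1 (log2 change -0.32), CDK2 (-0.31) and MLANA (0.03), and the explanation does not account for them. Promoter motifs were not searched, since no genome was used here. Of the melanocyte markers, a list without TYR, TRPM1 and TSPAN10, 2 of 12 (16.7%) rose and 1 fell (3 and 2 adjusted over the list alone), with TYRP1 at 6.61 in LacZ and 6.29 in TFEB arrays.

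Other interferon-induced genes, none of them in the fixed list but listed once its fall had been seen, fell in 29 of 39 measured members (34 adjusted over the list alone), with a median log2 change of -0.95 (camera adjusted p = 3.13e-24, and adjusted p = 0.104 with an estimated correlation). This list was written because the fixed list fell, so its count and test are not independent evidence. Its adjustment ran over the later lists alone. Both interferon lists together held 38 of the 99 genes that fell at least 2-fold (38.4%) and 51 of the 745 that fell. Type I interferons, their relatives and receptors changed in 1 of 16 measured members (IFNAR2, log2 change -0.37, adjusted p = 0.0480, a call lost when adjusted over the list alone), with a median of -0.08 (camera adjusted p = 0.275). Of these, 6 lay above the median gene level in LacZ arrays, and none of the 6 encodes an interferon. IFNB1 read 1.57 in LacZ and 1.25 in TFEB arrays, near the bottom of the scale. Whether interferon genes differed cannot be read from this list. Keratinocyte, melanocyte and B cell markers, lists without the risen genes IVL, TYR and CD79A, did not pass camera (adjusted p = 0.190, 0.284 and 0.354).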
